A study of Caenorhabditis elegans with 4 samples.

How the data were processed

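Chromatin immunoprecipitation with sequencing (ChIP-seq) was done on 2 replicates of N2 hermaphrodites at stage L3, each with a ChIP library and an input library. Per the labels' protocols, synchronized larvae were grown in liquid culture at 20 °C with bacteria as food and staged by developmental milestones, cross-linked with 2% formaldehyde, and lysed by sonication, and the recovered fragments were size-selected and prepared for Illumina sequencing. The sample labels name the antibody 8WG16 against RNA polymerase II. The shared protocol text speaks instead of an anti-GFP serum and of embryos, and the labels of the samples were followed.

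The file analysed was 1 list of peaks for the whole series, named by the authors as combined. Per the file headers, coordinates are on WormBase build WS180, and the list itself names PeakSeq as the caller. PeakSeq scores regions of ChIP reads against a scaled input. Its version, the aligner, the read filters and the way the replicates were combined are not given in the sources used here. Each row of the deposited list has a chromosome, a start, an end and a q-value, which is written in 2 places with identical text in all 6507 rows. The q-values are used only to rank and describe peaks within this list. All were below 0.01 in the list. Start and end were read as 1-based, closed positions, per the file headers (GFF3). No read counts, peak heights or summits were used, so the depth per sample and the precision it gives are unknown here. With no value per replicate, no replicate error, no test of ChIP against input and no analysis that leaves out a replicate could be made.

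The order of the deposited rows was checked against their q-values. The list does not run in order of q: q fell between 2502 of the 6506 neighbouring pairs of rows, while q times rank, counted down the rows, never fell. An order by p was inferred from this, since the list gives no p. The number of ranks before the first row was found from neighbouring rows with equal q times rank: 2414 pairs were equal (relative tolerance 1e-10) with 103 ranks placed before it, and 0 pairs with any other number from 0 to 500. The last row then has rank 6610. Regions at the first 103 ranks, 1.56% of that range, were not analysed here.

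The comparisons and tests were fixed before the data were examined, except for those named as added. Peaks were counted per chromosome, with exact 95% Poisson intervals, an exact binomial test of each chromosome against its share by length (Benjamini-Hochberg over 6), and a chi-square test with p from 100000 multinomial draws. Because no chromosome lengths were at hand for the build, the end of the last peak was taken as the length of a chromosome, which differs from the plan and gives 100 Mb in all. Chromosomes were divided into blocks of 1 Mb, leaving out a last block under 0.5 Mb, with each peak assigned by its midpoint. Blocks were permuted between X and the autosomes, and between chromosomes (100000 draws, two-sided for pairs of groups), and ratios of mean densities carry 95% bootstrap intervals over blocks (10000 draws). The centre of a chromosome was taken as the middle 33.3% of its length. The share of peaks in the centre was tested by 10000 random circular shifts of the peaks within each chromosome, which keep the spacing of peaks, and per-chromosome shares carry exact binomial intervals. Spacing was compared with 1000 random placements of the same widths without overlap. The comparison of q at matched width used 7 width classes and was added after the data were seen. So were the ratio and block test of chromosome I against the others, and all values without chromosome I. Also added were values for peaks above a given width, and the test of the centre's share of peaks on X against the autosomes. Intervals of counts cover counting error only and assume independent peaks.

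The plan also held promoter and gene-body classes, tests of fixed gene lists and the share of genes with a peak on each chromosome, to be run only with an annotation of the same build. The gene table at hand is of assembly WBcel235, a different build, so no peak was assigned to a gene and these were not run. The naming rule then gave peaks by position only: the 10 with the lowest q and the 10 widest. Alternatives were the best 50% and the best 25% of peaks by q, merging of peaks within 500 bp, covered base pairs in place of counts, blocks of 500 kb, blocks of the centre only, the middle 50% of the length in place of the middle 33.3%, spans from the first to the last peak, a distance of 2 kb, and leaving out the widest 1% of peaks.

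The tests were tried on simulated data, 100 sets per setting of clustered peaks with the real widths at about 40 peaks per Mb. With no difference, 4% of sets passed 0.05 in the test of the centre and 7% in that of X. A density 1.5 times higher in the centre was found in 95% of sets. A density on X of 0.8 times that of the autosomes was found in 44% of sets, and one of 0.5 times in 100%. Chromosome I was simulated at the density of the others, so these rates do not apply to the real comparison of X. With chromosome I left out of the simulated sets, 10% of sets passed with no difference on X, 40% at 0.8 times and 100% at 0.5 times. Broad differences in density along a chromosome, other than at the centre, were not simulated, so all these rates may be too favourable. The work was done in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and plots with matplotlib 3.10.9.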

Results

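The series mapped RNA polymerase II along the genome of Caenorhabditis elegans at the larval stage L3. Chromatin came from hermaphrodites of N2, the wild-type reference strain, grown at 20 °C. It was precipitated with the mouse monoclonal antibody 8WG16, which binds the repeated heptapeptide in the C-terminal domain of the largest polymerase subunit, the product of ama-1. The samples were 2 ChIP libraries and 2 libraries of input DNA, the unprecipitated chromatin that serves as background, 1 of each per replicate. A single combined list of peaks for the series, called with PeakSeq, was analysed, so each value below describes both replicates together. The list has no read counts and no value per replicate. The depth of the libraries is therefore unknown here, no spread between replicates could be computed, and intervals cover counting error or the spread between regions of the genome.

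The authors' list of regions called enriched for RNA polymerase II in L3 larvae was described first. No test of ChIP against input was made here. The list held 6507 peaks that did not overlap one another and together covered 5.72 Mb, or 5.72% of the summed span of the 6 nuclear chromosomes. Most peaks were short, with a median width of 354 bp and quartiles of 157 and 932 bp, while the median was 664 bp in the best 50% of peaks by q and 1378 bp in the best 25%. A smaller class of wide peaks held most of the covered sequence: 1553 peaks (23.9%) were at least 1 kb wide and held 73.5% of the covered base pairs. At the other end, 1090 peaks (16.8%) were under 100 bp, and 37 of them were 1 bp wide. The q values, which are the authors' own, ran from 1.86e-301 to 0.00999, and 239 peaks had a q below 1e-100. Wide peaks tended to have the lower q: Spearman's rho between width and −log10 q was 0.57 across peaks (permutation test, two-sided, p = 0.0001, the smallest that 10000 permutations can give), although peaks are not independent replicates.

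The 10 peaks with the lowest q lay on 5 chromosomes (coordinates on WormBase build WS180). Chromosome I held 3 of them, at 2667596 to 2671100, at 10560022 to 10565710 and at 2875084 to 2879155. Chromosome II held 3, at 9933097 to 9938741, at 8010866 to 8021403 and at 11633868 to 11638040. Chromosome V held 2, at 9342846 to 9346325 and at 16592118 to 16596625. Chromosome III held 1, at 1615896 to 1627078, and chromosome IV held 1, at 4235278 to 4237408. X held 0 of the 10. The q values of these 10 peaks ran from 1.86e-301 to 7.27e-285, and their widths from 2131 to 11183 bp. Ranks recovered from the q values place 103 regions before the first listed peak, so these are the lowest q values among the listed peaks and not necessarily the strongest regions of the experiment.

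The widest listed peak spanned 19973 bp on chromosome III, from 7718838 to 7738810, with a q of 1.03e-254. The next widest were 2 regions of chromosome II, of 14486 bp at 1232948 to 1247433 and of 12624 bp at 3951179 to 3963802. X held 2 of the 10 widest peaks, of 12288 bp at 16790802 to 16803089 and of 11682 bp at 8015383 to 8027064. Chromosome V held 2, of 12203 bp at 8415098 to 8427300 and of 10668 bp at 16776688 to 16787355. Chromosome IV held 1, of 10422 bp at 14789292 to 14799713. The remaining 2, the 11183 bp peak on chromosome III and the 10538 bp peak on chromosome II, were also among the 10 with the lowest q. Chromosome I, with the most peaks, held 0 of the 10 widest listed. The widths of the regions at the 103 unlisted ranks are unknown. These 10 are therefore not necessarily the widest regions of the experiment.

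Peaks were distributed very unevenly between chromosomes. Chromosome I held 3028 peaks, 46.5% of the list on 15.04% of the summed span, at 201 peaks per Mb (exact 95% Poisson interval 194 to 209). The other autosomes followed at 53.4 peaks per Mb on III (49.6 to 57.4), 48.7 on IV (45.5 to 52.1), 45.9 on II (42.5 to 49.4) and 28.0 on V (25.8 to 30.4), and X held 34.6 (31.9 to 37.4). In blocks of 1 Mb, chromosome I averaged 202 ± 41.9 peaks per Mb (SD over 15 blocks), 4.95 times the mean of the 85 blocks of the other chromosomes (bootstrap 95% interval 4.27 to 5.69). The test on blocks gave p = 1e-05 (permutation test, two-sided), the smallest that 100000 draws can give. Chromosome I was singled out for this test after its density was seen. Every full block of chromosome I, from 124 to 268 peaks, held more peaks than any full block elsewhere, where the highest held 93.

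**Figure D1:**
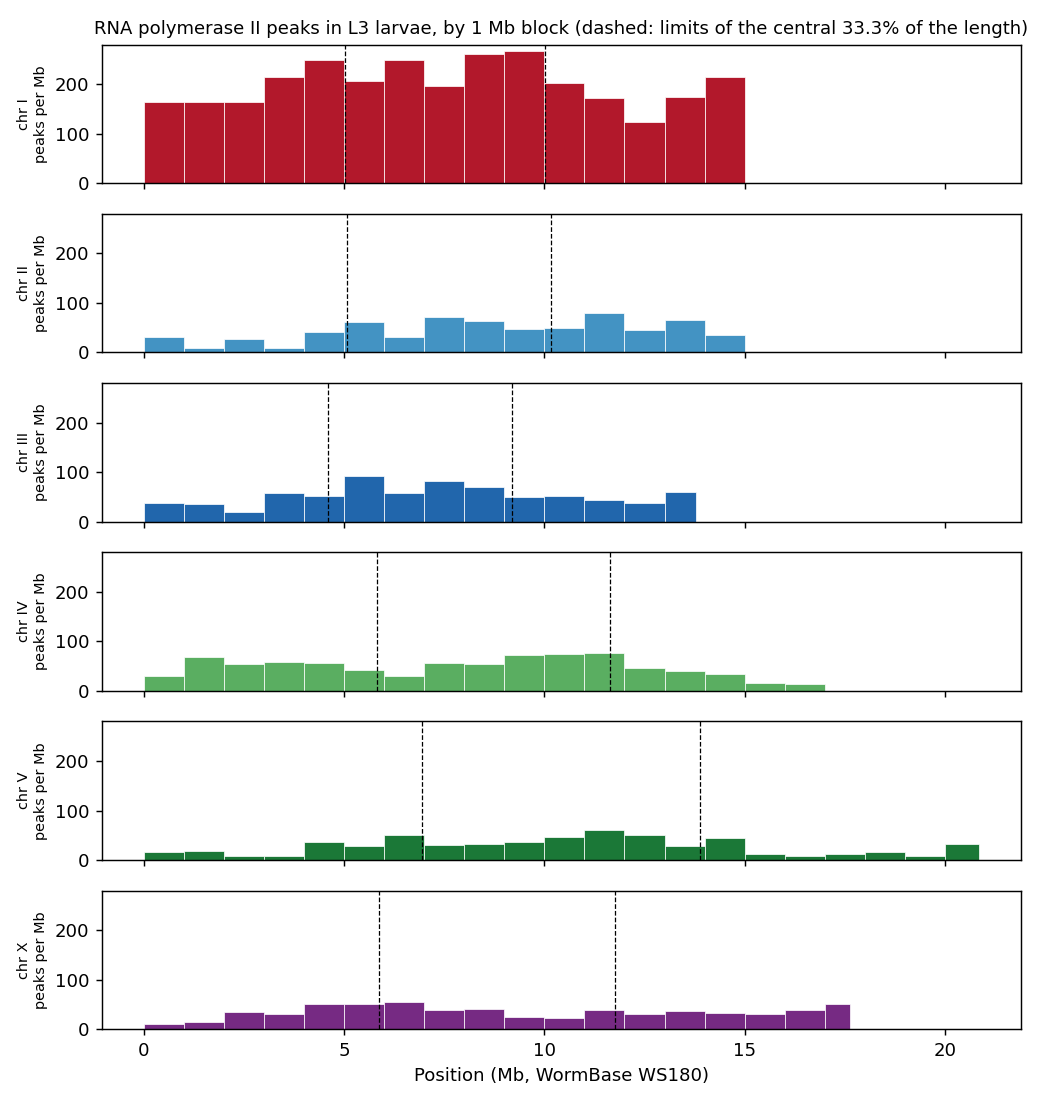
Peaks per Mb (vertical axis) in blocks of 1 Mb along each chromosome (horizontal axis, Mb on build WS180), 1 panel per chromosome, with dashed lines at the limits of the central 33.3% of its length. Blocks of chromosome I lie between 124 and 268 peaks, and the highest full block elsewhere, on chromosome III, holds 93.

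The excess on chromosome I consisted mainly of short peaks. The median width there was 242 bp, against 465 bp on III, 548 bp on II, 570 bp on V, 596 bp on IV and 720 bp on X. For peaks of at least 1 kb the densities were closer, at 20.7 per Mb on I, 18.1 on IV, 16.2 on III, 15.6 on II, 13.9 on X and 10.5 on V, and the ratio of chromosome I to the others fell to 1.43 (bootstrap 1.24 to 1.65, permutation p = 0.00058). Peaks of at least 3200 bp were sparsest on I, at 2.53 per Mb (1.79 to 3.47), against 3.45 on V (2.70 to 4.35) and 5.52 on III (4.35 to 6.91), and the ratio of chromosome I to the others was 0.566 (bootstrap 0.403 to 0.740, permutation p = 0.00211). That ratio rests on 38 peaks of chromosome I, fewer than the 103 unlisted ranks, which would raise its density to as much as 9.37 per Mb if all lay there. In covered sequence, chromosome I held 92.2 kb per Mb, III 61.6, IV 58.8, II 55.1, X 46.6 and V 38.3. Counting only peaks of at least 1 kb, covered sequence was 42.2 kb per Mb on I, below III (49.5), IV (47.9) and II (44.7) and above X (39.1) and V (32.6), with a ratio of I to the others of 1.01 (bootstrap 0.864 to 1.18, permutation p = 0.939). The effect of the unlisted ranks on this last ratio was not bounded.

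**Figure D2:**
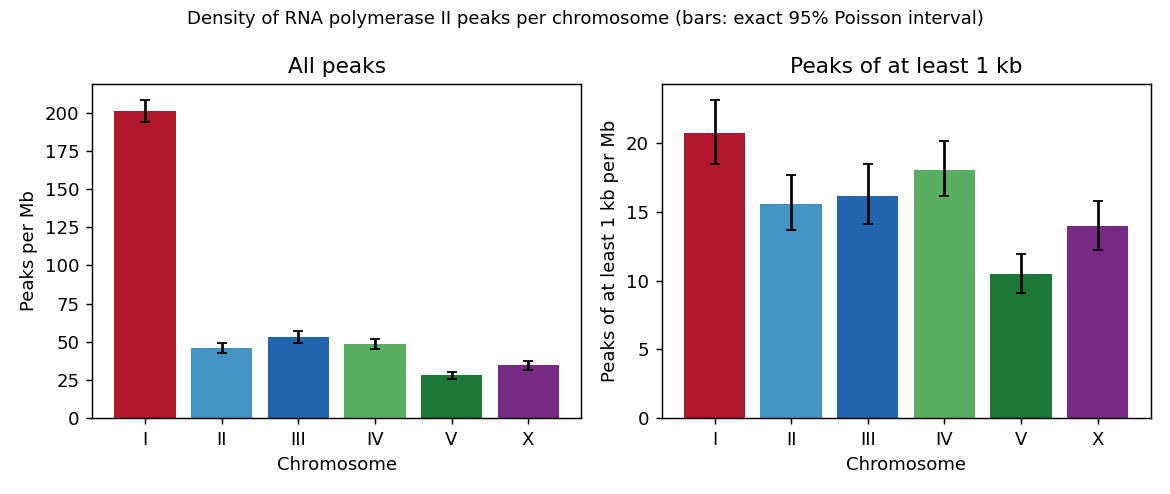
Peaks per Mb of each chromosome for all peaks (left) and for peaks of at least 1 kb (right), with exact 95% Poisson intervals as error bars. Chromosome I stands at 201 per Mb for all peaks and at 20.7 per Mb for those of at least 1 kb, where chromosome IV has 18.1.

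The q values also set chromosome I apart. Among peaks 400 to 799 bp wide, the median −log10 q was 17.3 for the 534 peaks of chromosome I and 4.27 for the 630 peaks elsewhere, where chromosome medians ran from 3.68 to 4.72. Among peaks 800 to 1599 bp wide, the medians were 37.6 and 6.53. The gap was smallest under 100 bp, at 4.08 against 3.26. When each peak's q was ranked as a percentile among peaks of its width class, with a higher percentile for a lower q, blocks of chromosome I had a mean of the block medians of 69.5 ± 10.1 (SD, 15 blocks) and blocks elsewhere 30.2 ± 7.62 (SD, 85 blocks; permutation p = 1e-05). The lowest block of chromosome I, at 54.6, lay above the highest block elsewhere, at 49.3.

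**Figure D3:**
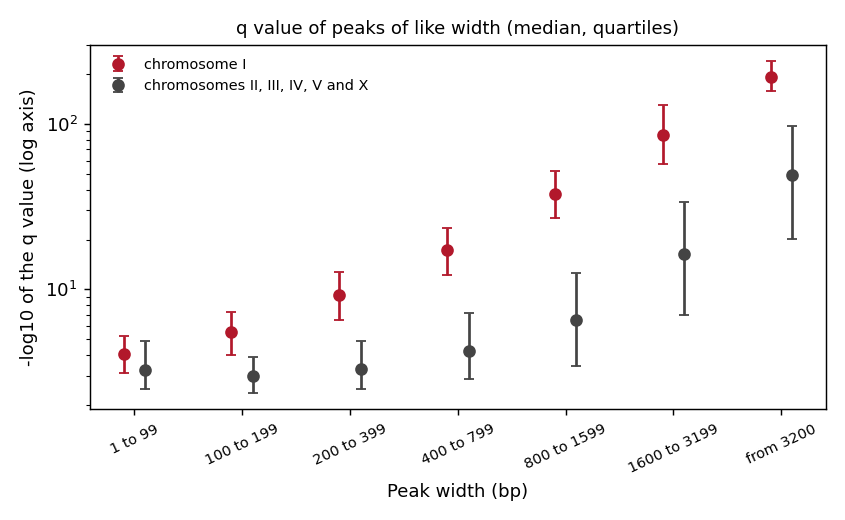
−log10 of the q value (log axis) against the width class of the peaks in bp, with points for the median and bars for the quartiles, for chromosome I and for the other 5 chromosomes together. From 200 bp upward the medians of chromosome I lie between 2.80 and 5.76 times those of the others.

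Among the other 5 chromosomes the densities also differed. The highest, on III, was 1.90 times the lowest, on V. The means of the chromosomes differed more than when 1 Mb blocks were permuted between them (permutation test on blocks, p = 0.00019, and p = 0.00518 for covered base pairs). Single blocks overlapped widely, from 20 to 93 peaks per Mb on III and from 8 to 60 on V. The same permutation test over all 6 chromosomes gave p = 1e-05. Tests that treat peaks as independent give p-values that are too small where peaks cluster. The permutation of blocks treats neighbouring blocks as independent, so its p-values can also be too small where density changes over several Mb. Each chromosome departed from its share by length in an exact binomial test, with the largest of the 6 Benjamini-Hochberg adjusted values, 3e-09, on chromosome III. Chromosome I lay above its share and the other 5 below. The shares are of the whole list, of which chromosome I held 46.5%, so it lowers those of the others. Chromosome III lay below its share, with 11.3% of peaks on 13.8% of the length, although it was the densest outside I. The multinomial chi-square test gave p = 1e-05 with and without chromosome I.

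X was then compared with the autosomes. In C. elegans hermaphrodites the X chromosomes are subject to dosage compensation in somatic cells and are largely silent in much of the germ line. X averaged 34.9 ± 12.2 peaks per Mb (SD, 18 blocks) and the autosomes 71.5 ± 67.1 (SD, 82 blocks), a ratio of 0.488 (bootstrap 0.378 to 0.632, permutation test on blocks, two-sided, p = 0.0211). In covered base pairs the ratio was 0.790 (permutation p = 0.0618), and in blocks of the chromosome centres alone 0.412 (permutation p = 0.0599), so neither passed the threshold. The size of this difference depended on chromosome I: without it the autosomes averaged 42.4 ± 21.1 peaks per Mb (67 blocks), and the ratio was 0.824 (0.670 to 1.00, permutation p = 0.155). For the best 50% by q of the peaks outside chromosome I it was 0.755 (0.595 to 0.938, permutation p = 0.0815). With the q limit of the best 50% of the whole list, which the low q values of chromosome I help to set and which 38.7% of the peaks elsewhere met, it was 0.707 (0.553 to 0.884, permutation p = 0.0417). For peaks of at least 1 kb without chromosome I the ratio was 0.955 (0.773 to 1.15, permutation p = 0.707). These ratios set X against the mean of the autosomes, and X was not below each of them. Chromosome V had 28.0 peaks per Mb against 34.6 on X, and 38.3 kb of covered sequence per Mb against 46.6. In the best 25% by q of the whole list V and X were alike, at 6.81 and 6.80 peaks per Mb. The spread here is between blocks, since X is a single chromosome. With chromosome I included, blocks of 500 kb gave nearly the same ratio, 0.480, with a lower p (permutation p = 0.00185). The p-value thus depends on the block size chosen. In sets simulated without chromosome I, the test on blocks passed in 10% with no difference on X.

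On the autosomes, peaks were more frequent in the chromosome centres than on the arms. The centres, taken as the middle 33.3% of the length of chromosomes I to V, held 2422 of their 5897 peaks (41.1%). When the peaks of each chromosome were shifted around it by random offsets, the mean was 33.4%, with 95% of shifts between 27.9 and 39.0% (permutation by circular shifts, two-sided, p = 0.0023). Without chromosome I the share was 43.3% (1241 of 2869 peaks, permutation p = 0.0175), and in the best 50% by q of the peaks outside chromosome I it was 41.7% and missed the threshold (permutation p = 0.0736). Each autosome had its share above the mean of its shifts, at 48.3% on V (exact 95% binomial interval 44.2 to 52.4), 45.0% on III (41.4 to 48.7), 41.01% on IV (37.7 to 44.4), 39.9% on II (36.3 to 43.7) and 39.0% on I (37.3 to 40.8). Tested alone, 0 of the 6 chromosomes passed after Benjamini-Hochberg adjustment: the lowest adjusted value was 0.0924, on III, whose unadjusted p was 0.0154.

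The densities of left and right arms were not tested against each other. On II the left arm had 24.0 peaks per Mb, the centre 54.9 and the right arm 58.6, each part being 33.3% of the length. On IV they were 52.7 on the left arm, 59.9 in the centre and 33.5 on the right arm. On III the values were 39.0, 72.1 and 49.0, on V 23.7, 40.6 and 19.7, and on I 191, 236 and 178. The densest full blocks outside chromosome I were 5 to 6 Mb on III with 93 peaks (exact Poisson 75.1 to 114) and 7 to 8 Mb on III with 83 (66.1 to 103), and the next were 11 to 12 Mb on II with 80 and 11 to 12 Mb on IV with 77. The sparsest was 3 to 4 Mb on V with 8 peaks (3.45 to 15.8), and 4 blocks held 9 each: 1 to 2 Mb on II, and 2 to 3, 16 to 17 and 19 to 20 Mb on V.

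X showed little difference between its centre and its ends, with 31.6, 36.6 and 35.6 peaks per Mb in the left, central and right parts. Its centre held 35.2% of its peaks (31.5 to 39.2), and the permutation by shifts gave p = 0.761. The share on the autosomes was 5.83 percentage points above that on X, a difference within the range that shifts alone gave (−11.8 to 9.45, permutation p = 0.324). Without chromosome I the difference was 8.01 points (−13.2 to 11.5, permutation p = 0.221). A difference between X and the autosomes in this respect was therefore not shown.

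Peaks lay close to one another more often than randomly placed peaks of the same widths. A neighbour within 1 kb was found for 3517 of the 6507 peaks (54.05%), against 21.3% on average over 1000 random placements (95% between 20.2 and 22.4%, two-sided permutation p = 0.000999, the smallest they can give). After peaks within 500 bp were merged, the share was 29.7%, against 15.5% at random. Merged peaks had no gaps of 500 bp or less, while the random placements could, so these shares are not like for like. Chromosome I had the highest share, 70.7%, where random placement gave 35.8%. On the other chromosomes together it was 39.6%, where random placement gave 8.67%, and single values ran from 32.5% on V to 43.8% on IV. The median gap between neighbouring peaks was 991 bp on chromosome I and between 4594 bp on IV and 10932 bp on V on the others.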

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

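Alternatives that leave out a chromosome, combine 2 choices, or keep only peaks above a width or merge them within 5 kb, and all those for the spread among II, III, IV, V and X, were chosen after seeing the data. So was the contrast of chromosome I with the others itself. The excess of chromosome I kept its direction and passed the test under 7 of 9 alternatives. Ratios ran from 1.43 for peaks of at least 1 kb to 8.06 for the best 50% by q, and covered base pairs gave 1.81. Selection by q favours chromosome I, whose q was lower at matched width, so the ratios by q are no independent check. The excess ended for base pairs covered by peaks of at least 1 kb (1.01, permutation p = 0.939), where the effect of the unlisted ranks was not bounded. It turned for peaks of at least 3200 bp (0.566, permutation p = 0.00211), where the 103 unlisted ranks outnumber the 38 such peaks listed on I. The spread among II, III, IV, V and X passed under 4 of 4 (ratios 1.54 to 1.87), closest to the threshold with the best 25% by q (permutation p = 0.049). X lay below the autosomes under 17 of 17 alternatives but missed the threshold of the permutation test under 8: covered base pairs (0.790, p = 0.0618), blocks of the centre only (0.412, p = 0.0599), peaks of at least 1 kb (0.887, p = 0.313), and, without chromosome I, all peaks (0.824), covered base pairs (0.902), peaks of at least 1 kb (0.955), and the best 50% (0.755) and 25% (0.759) by q of the remaining peaks. The loss for the central blocks goes with fewer blocks, 6 on X and 27 on autosomes. Without chromosome I, the q limit of the best 50% of the whole list gave 0.707 (permutation p = 0.0417). The share of autosomal peaks in the centre passed under 14 of 18 alternatives and missed the threshold of the permutation by shifts, without chromosome I, under the q limits of the best 50% (42.4%, p = 0.0598) and 25% (42.7%, p = 0.0849) of the whole list, and in the best 50% (41.7%, p = 0.0736) and 25% (43.1%, p = 0.06) of the remaining peaks, where fewer peaks remained. Spacing (6 alternatives) and the relation of width to q (3) kept direction and call, although merging within 500 bp moved the share with a neighbour within 1 kb to 29.7%. The number of peaks was 5022 after merging within 500 bp, and by construction 3254 in the best 50% and 1627 in the best 25%. Bounds for the unlisted ranks use peaks per Mb of whole chromosomes, not means over blocks. As listed, this ratio was 4.92 for chromosome I over the others and 0.812 for X over the autosomes without I. Wherever the 103 unlisted ranks lay, the former would stay between 4.78 and 5.08 and the latter between 0.784 and 0.949. The share of autosomal peaks in the centre would stay between 40.4 and 42.1%. Alternatives that need genes, summits or values per replicate were not run. No paired analysis was possible because the list has no value per replicate. Depth is unknown, so what it limits could not be assessed.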

Other observations

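The tests in this part were chosen after the results they concern were seen, except the merging of peaks within 500 bp, which was planned. Stretches of over 200 kb without a peak lay on II, IV, V and X. The longest ran over 747 kb on chromosome II, from 1473617 to 2220630 on build WS180. Chromosome V held the next 3, of 587 kb at 2731636 to 3318497, of 532 kb at 17348092 to 17879942 and of 525 kb at 2135832 to 2660374, and X held one of 505 kb at 1525584 to 2030551. V held 9 such stretches, X 6, and II and IV 4 each, while I and III held 0. The stretches of 587 and 525 kb lay between 2 and 4 Mb on V, in blocks of 9 and 8 peaks.

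The excess of peaks on chromosome I was weighed against 3 technical explanations. Splitting of wide peaks into narrower ones would raise the number of peaks without raising the sequence they cover. Covered sequence per Mb was 1.496 times that of the highest other chromosome, III (bootstrap 1.23 to 1.89), so splitting alone is argued against. Splitting as a part stays open. The ratio of chromosome I to the others fell from 4.95 to 4.08 when peaks within 500 bp were merged, and to 1.96 within 5 kb. Merging joins more peaks wherever they lie denser, split or not, so this fall cannot tell. A few dense regions are argued against as well, since the lowest full block of chromosome I held 1.33 times as many peaks as the highest full block elsewhere (124 against 93). A chromosome-wide difference in scoring, in the input used as control or in the number of reads could give lower q at matched width. The mean percentile on chromosome I was 39.3 points above that elsewhere, in blocks that did not overlap. A true excess of polymerase on chromosome I could lower q at matched width too, so this value cannot tell it from a technical difference. Which of these applies stays open, since read counts per chromosome were not analysed here, and the design has no second condition or stage in which a biological explanation could be tested.

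Neighbouring rows whose q falls are consistent with q computed as p times the number of regions over the rank, without a later step that makes q rise steadily. With 103 ranks before the first row, 2414 neighbouring pairs had equal q times rank (relative tolerance 1e-10), while each of the other 500 numbers of ranks tried, from 0 upward, gave 0 such pairs. A candidate explanation for the start after 103 ranks is that regions whose p was too small to be stored as a number fall outside the listed rows, since the lowest listed q is 1.86e-301; this was not tested, and their positions are unknown.

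The lower density of peaks on X was weighed against the excess of chromosome I as its source. Without chromosome I the ratio was 0.824 (bootstrap 0.670 to 1.00, permutation p = 0.155), so much of the difference went with chromosome I. A smaller deficit of X against the mean of the other autosomes stays open. Among the best 50% by q of the peaks outside chromosome I the ratio was 0.755 (0.595 to 0.938, permutation p = 0.0815), and for peaks of at least 1 kb 0.955 (permutation p = 0.707). It would not be a deficit against each autosome, since V had 28.0 peaks per Mb and X 34.6. In sets simulated without chromosome I a true ratio of 0.8 passed the test in 40% of cases, so a deficit of this size could be missed. Gene density and dosage compensation, which differ between X and the autosomes, were not tested.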
